A study of Glycine max with 16 samples.

How the data were processed

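Total RNA of the first fully expanded leaf of soybean, Glycine max cultivar Williams 82, was measured on 16 microarrays. Per the labels' protocols, plants grew at 22 °C with a 10 h photoperiod, 350 µmol per square metre per second of light and 60% relative humidity. Leaves of 4 plants were taken at each of 4 physiological states set by gas exchange. These states were the growth temperature (baseline), the temperature of the photosynthetic optimum, and the higher temperatures at which photosynthesis was 20% and 30% below that optimum. Air temperature was raised from 22 °C towards 42 °C by 2 °C every 10 min, and leaves were taken after a wait of 20 to 30 min at the wanted state. A whole curve lasted 3 to 4 h, so temperature and time since the start moved together. RNA from 100 mg of tissue was purified on a column with DNase, and 6 µg gave the biotin-labelled target, per the labels' protocols.

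The deposited values are linear signal intensities from MAS5, the Affymetrix algorithm that gives 1 intensity per probe set and array, per the submitters' processing notes. Its version, detection calls and background settings are not given in the sources used here. In each of the 16 arrays the mean of the 61170 intensities without the top and bottom 2% was 500.0, so the arrays had been scaled to a common level. Scaling to a common mean sets no change of total messenger RNA apart from array brightness. It can also press down other signals where some transcripts become very bright. The number of arrays, 4 per state, limits the precision, and no detection p-values were used here.

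The intensities were taken to log2 with no added constant and no further normalization. The 135 control probe sets were left out, which left 61035. Probe sets of other organisms were to be left out as well, but the annotation assigns no organism, so all 61035 entered the filter. Probe sets were tested where their mean log2 signal over the 16 arrays lay above the median of 6.08, a signal of 67.6, which left 30517. Each test was a two-sided moderated test in limma version 3.58.1 under R 4.3.3, with a mean per state fitted over all 16 arrays and a prior variance that followed the mean signal. The fit had 16.4 total degrees of freedom per probe set. Adjusted p-values are Benjamini-Hochberg values over the probe sets tested, with a threshold of 0.05. The contrasts were the 3 warmer states against baseline, 20% inhibition against the optimum, and 30% against 20% inhibition, and a moderated F-test asked for any difference among the states. The labels state 4 plants per state but not whether a plant gave leaves at several states, so the arrays were treated as independent.

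Gene names came from the array's platform annotation, which pairs 8677 probe sets with 1 gene and 370 with several, and lists none for 52123. A probe set with several genes was not named. Of the 8677, the gene identifiers of 8652 were found in a RefSeq table of the assembly Glycine_max_v4.0, which changed 0 symbols. The annotation gives symbols without titles, and 6795 probe sets carry only a locus number. Symbols or synonyms that name a product remained for 1882 probe sets of 1131 genes, and 936 of these genes were tested. The description of named genes and gene lists therefore covers a small part of the array. No genome build is given for the array in the sources used here, and no positions are given. Related soybean genes can bind the same probes, so a value for a member of a close family may include its relatives.

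Named genes were taken by a rule. A gene was represented by its tested probe set with the highest mean log2 signal. Those eligible had exactly 1 gene in the annotation with a product name, an adjusted p under 0.05, and no overlap between the 4 values of each state compared. From these the 10 largest rises and 10 largest falls were taken for 30% inhibition against baseline, 5 and 5 for the optimum and for 20% inhibition against baseline, and 3 and 3 for each step between successive states. Each gene list gave its 2 largest rises and 2 largest falls at 30% inhibition among members past the threshold, or its 2 brightest members where none passed.

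The themes of 39 gene lists, the tests, the filter, the rule for named genes and most alternatives were chosen before the data were examined. Because the annotation has no titles, the symbols that make up each list were written after the annotation was read and before any difference between states was computed. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, and again with an estimated correlation, where at least 5 probe sets were tested. This applied to 34 lists and 170 pairs of list and contrast, over which the p-values were adjusted. Counts adjusted over the list alone are given beside those over all probe sets tested.

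A background level was set per array as the 95th percentile of the signals of probe sets whose IDs begin with PsAffx or HgAffx. They were assumed not to target soybean, which no source used here states; the annotation pairs them with no gene, but it does so for many probe sets with soybean IDs as well. Each statement that a signal lies below background, and each bound, rests on this assumption. Where a gene lay below it on all 4 arrays of a state, its change is given as a bound, "at least N-fold". The bound sets the mean log2 signal of the brighter state against the mean of, per array, the higher of the background level and the gene's own signal. Control probe sets that report the 3′ and 5′ parts of the same transcript were compared between states with two-sided exact permutation tests. For GAPDH the 3′ probe set was set against the one marked M.

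Alternatives were quantile normalization, median centring, 32 added before log2, no filter, only probe sets above the upper quartile of mean signal, no trend of the prior variance, array weights, the replicate number as a block, a single probe set per gene, only the 8 arrays compared, and each array left out in turn. Chosen after seeing the data were a fit with only IDs that begin with Gma, GmaAffx or soybean, a fit without the 3 arrays of highest background, background as a covariate, and quantile normalization of the probe sets above the upper quartile.

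The fit was tested on simulated data drawn from the real means and spreads of 30517 probe sets, with 50 probe sets changed at each of 4 sizes. For 30% inhibition against baseline it recovered 8% of 50 changes of 0.5 log2 units, 44% of 50 changes of 1, 86% of 50 changes of 2 and 88% of 50 changes of 3, with 6 false calls. For 30% against 20% inhibition it recovered 10%, 50%, 84% and 92% of the same sizes, with 12 false calls. Far fewer probe sets were changed in the simulation than the 10579 that passed at 30% inhibition against baseline. The Benjamini-Hochberg cutoff was therefore stricter than in that real contrast, and the shares recovered do not carry over to it. A simulated list of 20 probe sets, shifted by 1 log2 unit at 30% inhibition, was called in 2 of 2 contrasts of that state. Of 173 other pairs of list and contrast 0 were called. The simulated probe sets varied independently, so these counts do not carry over to lists whose members are correlated. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.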

Results

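Leaf transcripts of soybean were measured at 4 points of a short warming curve, on 4 arrays per state. The states follow the leaf's transcripts as photosynthesis first reaches its temperature optimum and then becomes inhibited by heat. Log2 changes below are given ± the standard error of the limma fit with its adjusted p, with n = 4 arrays in each state, and signals are MAS5 intensities given as mean ± SD. Gene lists count probe sets, and several probe sets can report the same gene. Of all probe sets tested, 12.88% passed at the optimum, 35.6% at 20% inhibition and 34.67% at 30% inhibition against baseline. From the optimum to 20% inhibition 16.58% passed. In each contrast about as many were higher as lower. A list count near these shares is no response particular to that list. The largest component of variation over the tested probe sets took 37.9% of the variance. Of the 30517 probe sets tested, 10829 differed among the 4 states by the moderated F-test.

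Array properties also moved with the states. The background level, read from probe sets assumed not to target soybean, was 81.8 ± 7.0 at baseline, 86.2 ± 11.9 at the optimum, 125 ± 28.1 at 20% inhibition and 112 ± 30.8 at 30% inhibition (SD, n = 4). The exact permutation p of its log2 values against baseline was 0.6, 0.0286 and 0.0857, adjusted 0.771, 0.129 and 0.231. The 3′ minus 5′ log2 signal of the control probe sets named GlutTrans was 0.07 ± 0.25 at baseline and 0.80 ± 0.16, 0.90 ± 0.16 and 0.83 ± 0.13 in the warmer states in order (SD, n = 4, two-sided exact permutation p = 0.0286 for each against baseline, the smallest that 4 against 4 arrays allow, and 0.129 after Benjamini-Hochberg adjustment over 27 tests). That of the actin controls named r2 was 1.08 ± 0.06 at baseline, 1.18 ± 0.15 at the optimum, 1.40 ± 0.07 at 20% inhibition and 1.37 ± 0.07 at 30% inhibition (exact permutation p = 0.257, 0.0286 and 0.0286, adjusted 0.578, 0.129 and 0.129). The controls named actin without r2 stood at 4.44 ± 0.30 at baseline and lower, at 3.60 ± 0.67, at 20% inhibition (exact permutation p = 0.0571, adjusted 0.171). Those of GAPDH (3′ minus M), ubiquitin and SucBP had exact permutation p of at least 0.343 in each state. The SD within a state was 0.95 to 1.61 for ubiquitin and 0.75 to 2.73 for SucBP. A shift as large as that of GlutTrans could be missed in these 2.

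**Figure D1:**
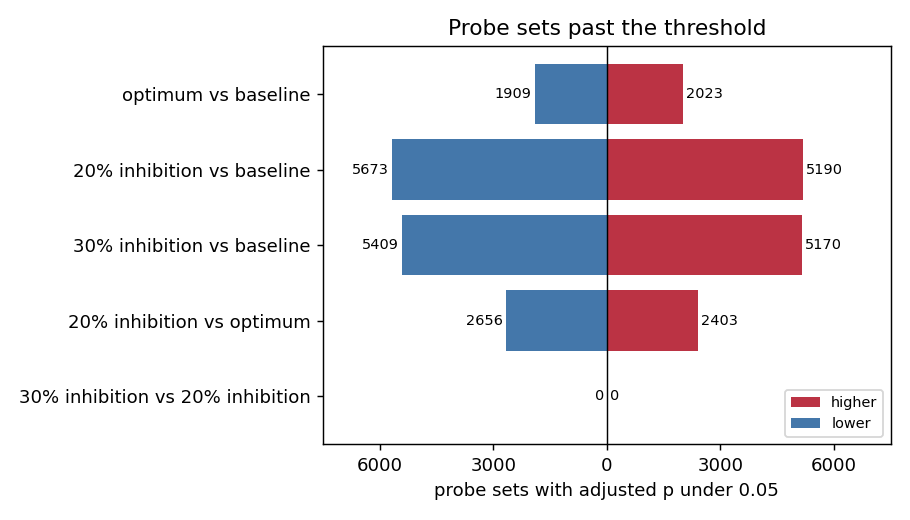
Probe sets with an adjusted p under 0.05 in each of the 5 contrasts, with those higher in the first-named state to the right and those lower to the left. The optimum gave 2023 higher and 1909 lower, while for 30% against 20% inhibition limma called 0 (1193 at an unadjusted p under 0.05, a smaller share than chance alone gives).

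At the photosynthetic optimum, 7 of 8 small heat shock protein and 9 of 10 HSP90 probe sets rose. HSP90A1, a cytosolic HSP90 chaperone, rose from a signal of 1770 ± 1110 to 19910 ± 4180 (SD), a log2 change of 3.64 ± 0.27 (adjusted p = 2.75e-07). The heat shock transcription factor genes HSF-26, HSF-03 and HSF-08 rose by 2.96 ± 0.28, 2.82 ± 0.25 and 2.67 ± 0.33, and the small heat shock protein gene HSP23.9 by 2.68 ± 0.16. Among genes named as MYB transcription factors, MYB118 fell by 2.88 ± 0.52, MYB114 by 2.69 ± 0.42 and MYB134 by 2.68 ± 0.16, and the WNK kinase gene WNK13 fell by 1.68 ± 0.26. MYB177 fell by 2.42 ± 0.60, with 1 of its 4 arrays at the optimum below background. Without optimum replicate 3 its change was -1.67. All these genes had adjusted p of at most 0.013, and the rule that picked them required no overlap between the 4 values of each state.

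By gene list, 7 of 8 small heat shock protein probe sets, of 4 genes, rose at the optimum (7 adjusted over the list alone), with a median change of 2.46 (camera adjusted p = 9.54e-14; adjusted p = 0.0934 with an estimated correlation). Of 10 HSP90 probe sets, of 2 genes, 9 rose, also adjusted over the list alone (adjusted p = 1.35e-15; adjusted p = 0.128 with an estimated correlation). Of 14 heat shock factor probe sets, of 10 genes, 4 rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 0.00554; adjusted p = 0.339 with an estimated correlation). ER protein folding rose at 6 of 14 probe sets, of 8 genes (6 adjusted over the list alone; adjusted p = 5.11e-06; adjusted p = 0.357 with an estimated correlation). BIP4, the ER-resident HSP70, rose by 1.53 ± 0.14 and the protein disulfide isomerase gene PDIM-1 by 0.98 ± 0.13. Aquaporins, which are water channels, had 8 of 38 probe sets, of 22 genes, higher and 1 lower (12 and 3 adjusted over the list alone; adjusted p = 0.0128; adjusted p = 0.696 with an estimated correlation), and PIP1-4 rose by 1.12 ± 0.22. Dehydration and abscisic acid genes had 4 of 8 probe sets, of 6 genes, higher (4 adjusted over the list alone; adjusted p = 0.0148; adjusted p = 0.314 with an estimated correlation), with ERD15 up by 1.57 ± 0.16. In the circadian clock and photoperiod list 0 of 10 probe sets, of 8 genes, rose and 3 fell (1 and 5 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.0182; adjusted p = 0.272 with an estimated correlation). MYB factors had 6 of 71 probe sets, of 53 genes, higher and 14 lower (9 and 18 adjusted over the list alone; adjusted p = 0.0271; adjusted p = 0.545 with an estimated correlation). Calls of 4 lists ended without a single array. These were dehydration without baseline replicate 4 (adjusted p = 0.0552), the clock without optimum replicate 1 (0.0552), aquaporins without baseline replicate 2 (0.0544) or 4 (0.0516), and MYB factors without baseline replicate 2 (0.198) or optimum replicate 1 (0.0621).

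In all, 3932 probe sets passed at the optimum against baseline, 2023 higher and 1909 lower, of which 645 and 593 changed at least 2-fold. Groups did not overlap for 6005 of 30517 probe sets, against 2.86% by chance. List calls that ended under other settings with the preset correlation, with the range of adjusted p over all alternatives with that correlation, were those of heat shock factors (0.000268 to 0.0628) and aquaporins (0.000976 to 0.103) with 1 probe set per gene, of dehydration (0.00206 to 0.323) and the clock (0.0019 to 0.167) with 1 probe set per gene or only above the upper quartile of signal, and of MYB factors (0.00812 to 0.572) in these or with no filter. The GlutTrans control difference given above was also higher at the optimum than at baseline on every array.

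At 20% inhibition against baseline, all 8 small heat shock protein and 9 of 10 HSP90 probe sets rose. HSP22.5 lay below background on all 4 baseline arrays and reached 4650 ± 838 (SD), at least 56.3-fold higher (adjusted p = 2.91e-10). HSP22.3 rose by 7.27 ± 0.16, HSP17.5-E by 7.24 ± 0.18 to a signal of 52720 ± 3134, and BAG6A, a BAG-domain cochaperone gene, by 7.04 ± 0.64, being below background on 3 of 4 baseline arrays (6.25 without baseline replicate 1, and 5.71 with signals below background set at that level). SACPD-C, a stearoyl-ACP desaturase gene, was at least 21.5-fold higher (adjusted p = 1.59e-05). MYB114, which the RefSeq table also names GmLHY2b, a clock gene of the LHY type, was at least 26.6-fold lower. MYB134 fell by 5.53 ± 0.16, the asparagine synthetase gene AS2 by 3.72 ± 0.29 and MYB186 by 3.68 ± 0.19, and MYB118 fell by 3.66 ± 0.52. At 20% inhibition MYB118 lay below background on 2 of 4 arrays, and MYB134 and AS2 on 1 each.

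Of the lists at 20% inhibition, all 8 small heat shock protein probe sets rose, also adjusted over the list alone (adjusted p = 4.94e-16; adjusted p = 0.0678 with an estimated correlation), with a median of 6.92, or 6.20 with members below background set at their bound. HSP90 rose at 9 of 10 probe sets, also adjusted over the list alone (adjusted p = 8.68e-08; adjusted p = 0.266 with an estimated correlation). Heat shock factors rose at 8 of 14 (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.000991; adjusted p = 0.266 with an estimated correlation). ER protein folding rose at 6 of 14 and fell at 1, also adjusted over the list alone (adjusted p = 0.000991; adjusted p = 0.593 with an estimated correlation). Dehydration and abscisic acid genes rose at 5 of 8, also adjusted over the list alone (adjusted p = 0.00394; adjusted p = 0.266 with an estimated correlation). The clock and photoperiod list fell at 7 of 10 and rose at 1, also adjusted over the list alone (adjusted p = 0.00436; adjusted p = 0.266 with an estimated correlation). Nitrogen assimilation fell at 9 of 18 probe sets, of 10 genes, also adjusted over the list alone (adjusted p = 0.00295; adjusted p = 0.217 with an estimated correlation). Ubiquitin and proteasome genes fell at 4 of 16 probe sets, of 7 genes (4 adjusted over the list alone; adjusted p = 0.0363; adjusted p = 0.508 with an estimated correlation), a list call that ended without baseline replicate 2 (0.0734) or 20% inhibition replicate 1 (0.0787). Flavonoid and phenylpropanoid synthesis fell at 24 of 57 probe sets, of 29 genes, and rose at 3 (26 and 3 adjusted over the list alone; adjusted p = 0.00634; adjusted p = 0.631 with an estimated correlation). In total 10863 probe sets passed, 5190 higher and 5673 lower, with 1941 and 2146 changed at least 2-fold, and groups did not overlap for 9888 of 30517, against 2.86% by chance. The count was 7070 with array background as a covariate. Replicate 3 of this state stood apart, with the highest background of the 16 arrays (163), the lowest array weight (0.433) and a median correlation of 0.835 with the other arrays (0.857 to 0.894 for the 15 others), and 10285 probe sets passed without it. List calls that ended under other settings with the preset correlation, with the range of adjusted p over all alternatives with that correlation, were those of ER protein folding (1.74e-05 to 0.0633) and dehydration (0.000185 to 0.103) with 1 probe set per gene, and of flavonoid synthesis (9.52e-05 to 0.0897) only above the upper quartile of signal. Those of the clock (2.46e-05 to 0.0985) and of ubiquitin and proteasome genes (0.00104 to 0.106) ended in both, and the latter also with background as a covariate or without the 3 arrays of highest background. The background level and the GlutTrans and actin r2 control differences given above moved with the state as well.

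At 30% inhibition against baseline, all 8 small heat shock protein and 9 of 10 HSP90 probe sets rose. HSP22.5 was at least 49.4-fold higher, at 4421 ± 2090 against a baseline below background on all 4 arrays (adjusted p = 4.1e-10). HSP17.5-E rose by 7.14 ± 0.18, HSP22.3 by 7.02 ± 0.16, and SB100, the soybean HSP101 gene whose protein frees aggregated proteins, by 5.58 ± 0.29. BAG6A rose by 6.81 ± 0.64 (6.02 without baseline replicate 1), being below background on 3 of 4 baseline arrays, and by 5.47 with signals below background set at that level. HSP90A1 rose by 5.24 ± 0.27 to 59670 ± 7068 and HSP23.9 by 3.60 ± 0.16 to 44150 ± 6030, while the brightest signal on any array was 89579. HSF-08 rose by 3.67 ± 0.33. SACPD-C was at least 18.2-fold higher, on a single probe set whose 4 arrays gave 2033 ± 1646 (SD), and PGMPM19 was at least 2.15-fold higher (adjusted p = 0.000367), with 2 of its 4 arrays at 30% inhibition still below background.

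All 8 small heat shock protein probe sets rose at 30% inhibition, also adjusted over the list alone, with a median change of 6.90, or 6.21 with members below background set at their bound (camera adjusted p = 4e-16; adjusted p = 0.0678 with an estimated correlation). HSP90 rose at 9 of 10 (9 adjusted over the list alone; adjusted p = 1.96e-08; adjusted p = 0.266 with an estimated correlation), with HSP90-1 up by 0.86 ± 0.14. Heat shock factors rose at 8 of 14 probe sets (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.000527; adjusted p = 0.266 with an estimated correlation), HSF-26 by 3.08 ± 0.28. The ER protein folding list rose at 6 of 14 (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.000234; adjusted p = 0.545 with an estimated correlation), with PDIM-1 up by 2.04 ± 0.13 and BIP4 by 1.98 ± 0.14. Among HSP70 and BiP genes 2 of 3 probe sets, of 2 genes, rose (3 adjusted over the list alone), and the chaperonin gene CCT-D fell by 0.66 ± 0.10. Immunophilins and cochaperones went both ways, with 6 of 17 probe sets, of 13 genes, higher and 5 lower (8 and 5 adjusted over the list alone). The cyclophilin gene CYP17 rose by 1.68 ± 0.13 while CYP11 and CYP26 fell by 1.18 ± 0.16 and by 1.08 ± 0.15.

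**Figure D2:**
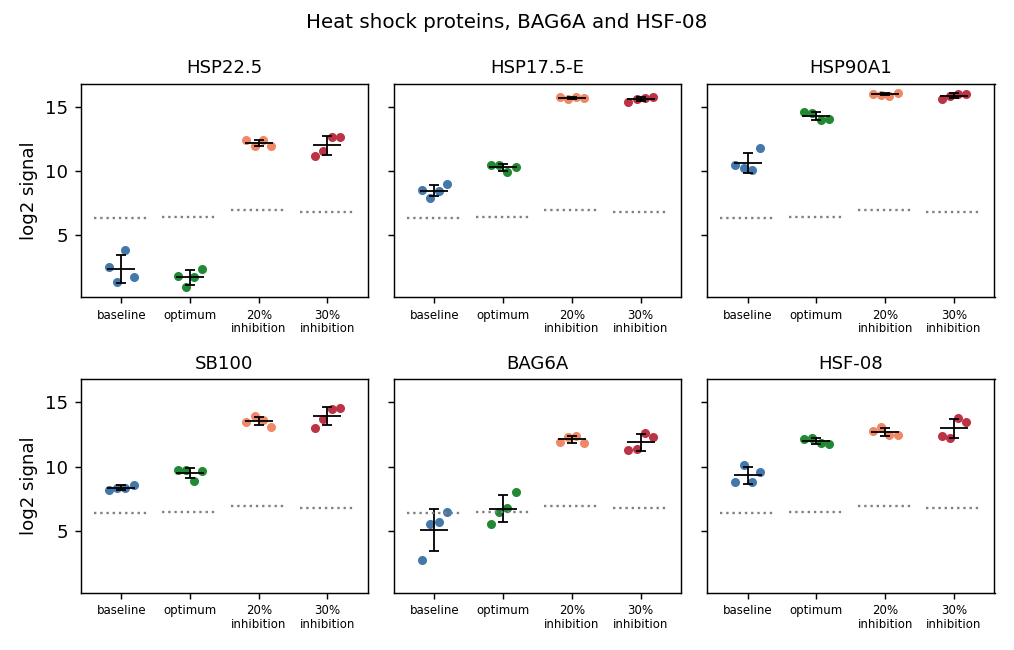
Log2 MAS5 signal of 6 genes on each array (points) in the 4 states, with the mean and SD of 4 arrays in black and the mean background level of the state as a dotted line. HSP22.5 lay below background at baseline and at the optimum and reached 4650 ± 838 at 20% inhibition, while HSP90A1 had already risen by 3.64 log2 units at the optimum.

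In the clock and photoperiod list 7 of 10 probe sets fell at 30% inhibition and 1 rose, also adjusted over the list alone (adjusted p = 0.003; adjusted p = 0.256 with an estimated correlation). LHY, a morning-expressed MYB factor of the circadian clock, fell from 10400 ± 570 at baseline to 724 ± 68.5 (SD) at 30% inhibition, a log2 change of -3.85 ± 0.16 (adjusted p = 4.86e-11). MYB114 was at least 30.0-fold lower and LCL3 fell by 2.84 ± 0.67, with 2 of its 4 arrays at 30% inhibition below background. LUXC, of the evening-expressed LUX type, rose by 2.69 ± 0.18 (adjusted p = 9.78e-09). MYB134 fell by 6.04 ± 0.16, with 2 of its 4 arrays at 30% inhibition below background, and MYB186 fell by 3.54 ± 0.19. The RefSeq table lists MYB134 among the other names of MYB114 and MYB186 among those of LCL1, another LHY gene, while the array's annotation pairs these probe sets with separate gene entries.

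**Figure D3:**
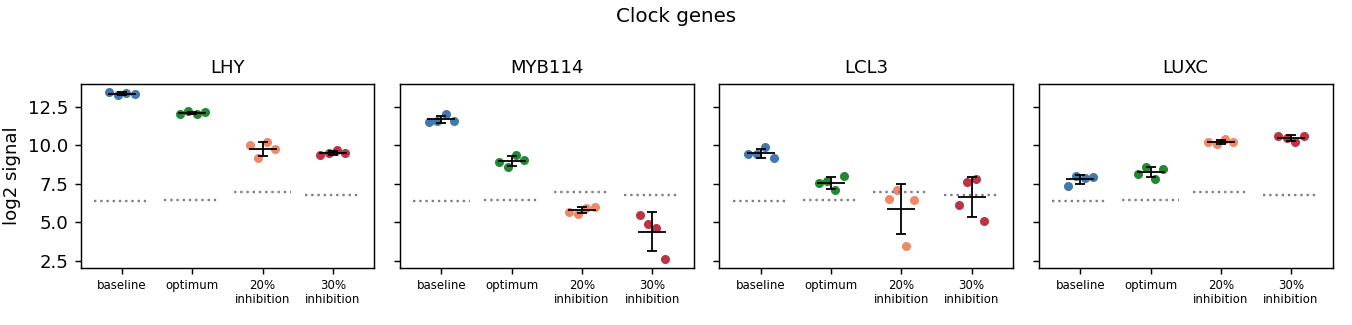
Log2 MAS5 signal of 4 clock genes on each array (points) in the 4 states, with the mean and SD of 4 arrays in black and the mean background level of the state as a dotted line. LHY fell by 3.85 log2 units and LUXC rose by 2.69 at 30% inhibition against baseline.

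Nitrogen assimilation fell at 9 of 18 probe sets at 30% inhibition (10 adjusted over the list alone; adjusted p = 0.0187; adjusted p = 0.266 with an estimated correlation), and AS2 fell by 4.08 ± 0.29. The ammonium transporter gene AMT1.3 fell by 3.15 ± 0.51. Flavonoid and phenylpropanoid synthesis fell at 19 of 57 and rose at 4, also adjusted over the list alone (adjusted p = 0.00786; adjusted p = 0.631 with an estimated correlation). The isoflavone synthase gene IFS1 fell by 2.80 ± 0.23 and the flavonol synthase gene FLS1 by 2.53 ± 0.22, while the chalcone reductase genes CHR4 and CHR5 rose by 2.15 ± 0.19 and 1.98 ± 0.57 (CHR5 1.35 with background as a covariate, no longer past the threshold). The Calvin cycle and Rubisco activase list had 4 of 6 probe sets, of 4 genes, lower (4 adjusted over the list alone), the activase genes RCA14 and RCAALPHA by 0.55 ± 0.12 and by 0.53 ± 0.13, though the list's test did not pass (adjusted p = 0.0552; adjusted p = 0.634 with an estimated correlation). Photosystem and light harvesting genes fell at 2 of 12 probe sets, of 5 genes (2 adjusted over the list alone), among them ELIP, an early light-induced protein gene, by 2.62 ± 0.21, with a list median of 0.13 and a mean of -0.26. SHMT, of the photorespiratory pathway, fell by 1.60 ± 0.20, 1 of 2 probe sets tested in its list and also adjusted over the list alone. Starch and sucrose metabolism had 5 of 11 probe sets, of 5 genes, lower (6 adjusted over the list alone), with SS and the beta-amylase gene BMY2 down by 1.01 ± 0.19 and by 0.87 ± 0.17.

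Among stress and hormone genes, the dehydration and abscisic acid list rose at 5 of 8 (5 adjusted over the list alone; adjusted p = 0.00804; adjusted p = 0.272 with an estimated correlation), ERD15 by 2.02 ± 0.16 and MAT1 by 1.33 ± 0.34. In the ethylene and ERF/DREB list 6 of 20 probe sets, of 13 genes, rose and 2 fell, also adjusted over the list alone. DREB2A2, a DREB-type transcription factor gene, rose by 3.37 ± 0.31 and DREB by 0.99 ± 0.17, while EREB fell by 1.17 ± 0.16. The jasmonate and wounding list had 7 of 40 probe sets, of 17 genes, higher and 7 lower, also adjusted over the list alone, with a median of 0.04 and a mean of -0.06. CYP74A2, of the allene oxide synthase family, and the jasmonate receptor gene COI1 rose by 1.37 ± 0.13 and 0.83 ± 0.11, while the allene oxide cyclase genes AOC4 and AOC3 fell by 1.52 ± 0.28 and by 1.38 ± 0.31. Gibberellin and brassinosteroid genes had 6 of 27 probe sets, of 20 genes, higher and 4 lower (6 and 4 adjusted over the list alone), with GASA22 and GASA27 up by 2.59 ± 0.34 and 0.95 ± 0.21 and the DELLA gene GAI1 down by 1.02 ± 0.23. Auxin genes had 1 of 9 probe sets, of 7 genes, higher and 0 adjusted over the list alone. Antioxidant enzymes had 5 of 18 probe sets, of 11 genes, higher and 2 lower (5 and 2 adjusted over the list alone), with the ascorbate peroxidase gene APX1 up by 0.83 ± 0.14. Glutathione S-transferases had 13 of 43 probe sets, of 29 genes, higher and 5 lower (13 and 5 adjusted over the list alone), from GSTU42 and GSTU28, up by 3.59 ± 0.96 and 2.63 ± 0.65, to GSTU3 and GSTU1, down by 1.61 ± 0.20 and by 0.95 ± 0.17. GSTU42 lay below background on 2 of 4 baseline arrays, and its change was 2.86 without baseline replicate 3 and 4.51 without baseline replicate 4. Defence genes had 11 of 105 probe sets, of 57 genes, higher and 12 lower (10 and 12 adjusted over the list alone), with a median and a mean of 0.01 and a list test that pointed down. WRKY63 rose by 2.56 ± 0.75, with 3 of 4 baseline arrays below background (2.41 with background as a covariate, no longer past the threshold). With signals below background set at that level its change was 1.57. WRKY8 and WRKY28 fell by 1.61 ± 0.37 and by 1.54 ± 0.21, WRKY8 with 3 of 4 arrays at 30% inhibition below background (-1.15 with signals below background set at that level).

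bZIP factors rose at 23 of 87 probe sets, of 58 genes, and fell at 6, also adjusted over the list alone (adjusted p = 0.0384; adjusted p = 0.266 with an estimated correlation), with BZIP105 and BZIP61 up by 2.69 ± 0.19 and 1.84 ± 0.35 and BZIP83 down by 1.01 ± 0.25. BZIP61 lay below background on 3 of 4 baseline arrays (1.38 with signals below background set at that level) and BZIP83 on 1 of 4 at 30% inhibition. NAC factors rose at 12 of 33 probe sets, of 18 genes, and fell at 3 (14 and 3 adjusted over the list alone; adjusted p = 0.0183; adjusted p = 0.694 with an estimated correlation), NAC32 by 1.58 ± 0.34. MYB factors had 13 of 71 higher and 24 lower (16 and 25 adjusted over the list alone), with MYB13 and MYB127 up by 2.18 ± 0.39 and 1.88 ± 0.19 and MYB118 down by 3.21 ± 0.52 (-2.57 without 30% inhibition replicate 4, the only array of that state on which it lay below background).

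Membrane and wall genes differed in direction. Aquaporins had 11 of 38 probe sets higher and 6 lower, also adjusted over the list alone, with a median of 0.13 and a mean of -0.08. PIP1-4 rose by 2.65 ± 0.22 and SIP1-6 fell by 2.67 ± 0.50. Fatty acid desaturases and lipid transfer genes had 4 of 10 probe sets, of 8 genes, higher and 5 lower (4 and 5 adjusted over the list alone), with a median of -0.71 and a mean of 0.095. FAD2-2 rose by 0.74 ± 0.12 and FAD6.1 fell by 2.67 ± 0.23, and FAD3C fell by 1.85 ± 0.49 (-1.48 with background as a covariate, no longer past the threshold). Cell wall genes had 1 of 6 probe sets, of 5 genes, higher and 3 lower (1 and 3 adjusted over the list alone). XET1 rose by 1.38 ± 0.20 and the expansin gene EXP2 fell by 1.29 ± 0.37 (-1.20 with background as a covariate, no longer past the threshold). Ribosomal protein genes had 4 of 10 probe sets, of 4 genes, lower (5 lower and 1 higher adjusted over the list alone), RPL37 by 0.56 ± 0.14 and RPL2 by 0.38 ± 0.10. Ubiquitin and proteasome genes had 3 of 16 lower (2 adjusted over the list alone), GRR1 by 0.83 ± 0.13 and SKIP16 by 0.48 ± 0.11. Calcium signalling genes had 5 of 16 probe sets, of 8 genes, lower (5 adjusted over the list alone). Cryptochromes and phytochromes had 1 of 6 probe sets, of 5 genes, higher and 2 lower (1 and 2 adjusted over the list alone), with a median of 0.00 and a mean of -0.04. GmCRY2c rose by 0.88 ± 0.12, while CRY2B and GmCRY1c1 fell by 0.68 ± 0.18 and by 0.50 ± 0.14. Of 6 alternative oxidase and uncoupling probe sets, of 3 genes, 1 was lower (0 adjusted over the list alone). H4, placed in the histone list by its name alone, changed by 1.56 ± 0.71 without passing (adjusted p = 0.102), though it is counted adjusted over the list alone. Without gene titles, whether this probe set reports a histone is not known.

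Lists planned as markers of other organs and tissues were read in the same leaves. Members such as PM37, SUT1, VSPA and LOXB1 were well above background on all 4 baseline arrays. Changes of these members are therefore by themselves no sign of other tissues in the samples. This does not hold for each member, since PM12 lay below background on all 4 baseline arrays. Whether other tissues were present was not tested. Seed storage and oil body markers had 5 of 16 probe sets, of 12 genes, higher and 3 lower (6 and 6 adjusted over the list alone), with PM37 up by 1.60 ± 0.11, PM12 at least 1.59-fold higher (1 of its 4 arrays at 30% inhibition below background) and PM23 down by 1.06 ± 0.10. Of 6 nodule and root marker probe sets, of 5 genes, that of NOD33 alone passed, up by 2.31 ± 0.22 (1 adjusted over the list alone). Phloem and xylem markers had 1 of 11 probe sets, of 7 genes, higher and 3 lower (1 and 3 adjusted over the list alone), and the sucrose transporter gene SUT1 fell by 1.08 ± 0.17. Of 14 vegetative storage protein probe sets, of 3 genes, limma called 0, also adjusted over the list alone, with a median of 0.04 and a mean of -0.04, LOXB1 at 0.10 ± 0.13 (-0.04 with quantile normalization) and VSPA at -0.10 ± 0.17 (0.01 with background as a covariate).

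Other named members of these lists passed at 30% inhibition, but their calls ended when a single array was left out. SODB2, a superoxide dismutase gene, rose by 0.31 ± 0.11 (0.26 to 0.32 without baseline replicate 1, 2 or 4 or 30% inhibition replicate 2, 3 or 4). The auxin list's ADR12 rose by 0.50 ± 0.17 (0.42 to 0.52 without baseline replicate 1 or 4 or 30% inhibition replicate 2, 3 or 4). PR1-7, named for a pathogenesis-related protein, rose by 2.72 ± 0.81 (2.35 without 30% inhibition replicate 1). The aquaporin gene GmTIP2;3 rose by 1.62 ± 0.54 (1.29 to 1.46 without baseline replicate 2 or 4 or 30% inhibition replicate 1 or 3). NAC018 rose by 1.12 ± 0.39 (0.75 to 1.09 without baseline replicate 1 or 3 or 30% inhibition replicate 1 or 2). The phloem marker SEO-F3 rose by 0.80 ± 0.30 (0.55 to 0.89 without baseline replicate 2, 3 or 4 or 30% inhibition replicate 1 or 3). The glutamine synthetase gene GS1GAMMA2 fell by 2.07 ± 0.62, below background on 3 of 4 arrays at 30% inhibition, and missed the threshold without baseline replicate 2 (-1.85). It changed by -1.28 without 30% inhibition replicate 2 and by -2.71 without 30% inhibition replicate 1. The DELLA gene GAI2 fell by 0.54 ± 0.20 (-0.43 to -0.59 without baseline replicate 1, 2 or 3 or 30% inhibition replicate 1, 2 or 4). The expansin gene EXP4 fell by 1.20 ± 0.40 (-0.94 to -1.19 without baseline replicate 1 or 3 or 30% inhibition replicate 2, 3 or 4). The calmodulin gene SCAM-2 fell by 0.29 ± 0.10 (-0.24 to -0.29 without baseline replicate 3 or 4 or 30% inhibition replicate 1 or 4). AOX2, an alternative oxidase gene, fell by 0.38 ± 0.14 (-0.29 to -0.38 without baseline replicate 1, 2 or 3 or 30% inhibition replicate 3 or 4). BZIP125 fell by 0.72 ± 0.23 (-0.58 to -0.67 without baseline replicate 2 or 3 or 30% inhibition replicate 3 or 4). The Kunitz trypsin inhibitor gene KTI-2 fell by 0.89 ± 0.31 (-0.66 to -0.94 without baseline replicate 1, 2 or 3 or 30% inhibition replicate 2 or 3). The aquaporin gene PIP2-1 lay below background on all 4 arrays at 30% inhibition and was at least 1.83-fold lower. Its fitted log2 change, -2.41, did not pass without baseline replicate 1 or 3 or without any array of 30% inhibition (-2.06 to -2.65). With background as a covariate the calls of all genes of this paragraph but GmTIP2;3 ended (KTI-2 -0.39, SEO-F3 0.53). Without the 3 arrays of highest background those of SODB2, ADR12, SEO-F3 (0.55), EXP4, BZIP125 and KTI-2 ended. With no filter those of SODB2, ADR12, SEO-F3, GAI2, SCAM-2, AOX2 and PIP2-1 ended, with no trend of the prior variance those of GAI2, AOX2, KTI-2 and PIP2-1, in the fit of only the 8 arrays compared those of SODB2, SEO-F3 and KTI-2, with the replicate number as a block those of ADR12, NAC018, SCAM-2 and AOX2, with quantile normalization those of SODB2 (0.16) and GAI2, and with array weights that of SEO-F3 (0.67).

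**Figure D4:**
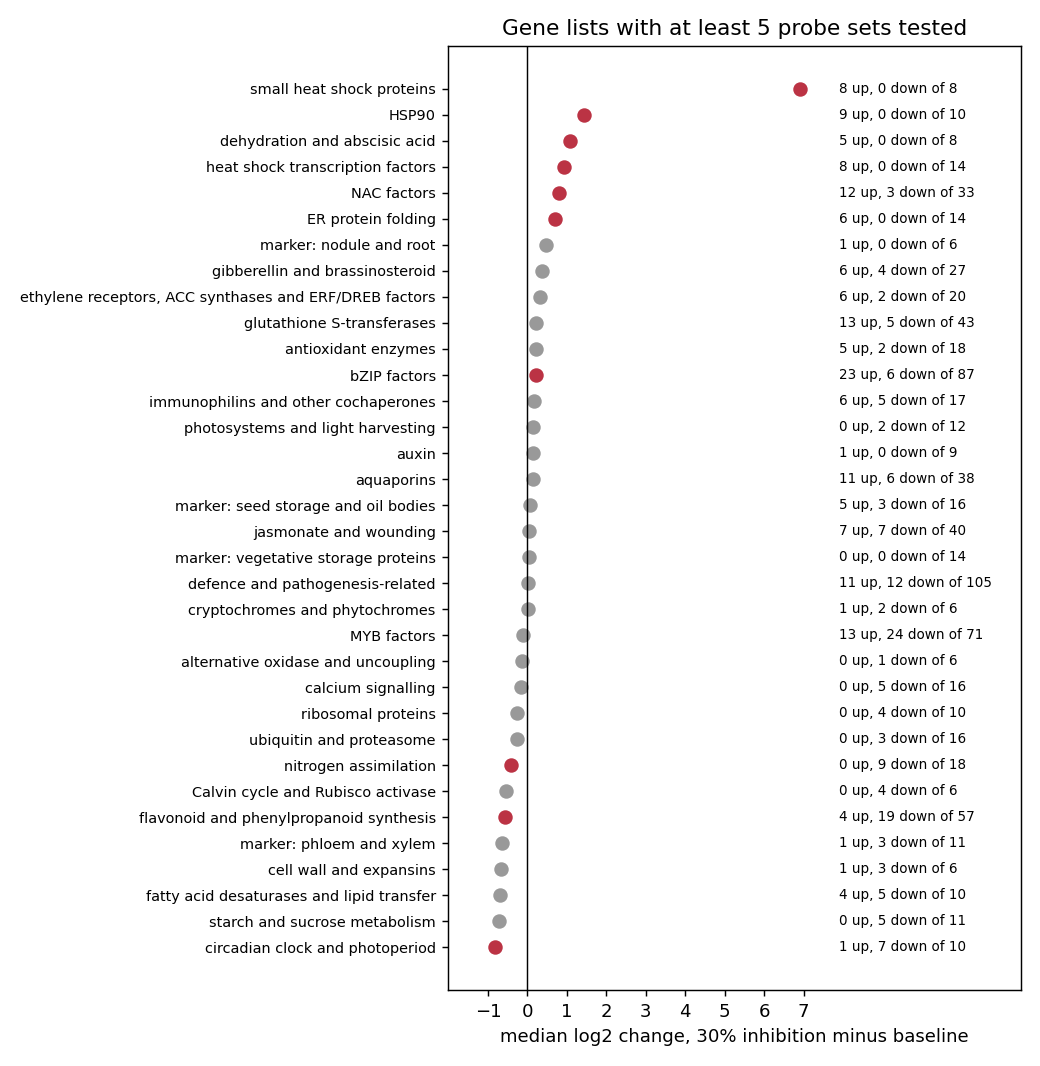
Median log2 change of each gene list with at least 5 probe sets tested, 30% inhibition minus baseline, with red points for lists whose camera adjusted p with the preset correlation was under 0.05 and grey points for the others. The counts at the right give members higher and lower past the threshold of those tested; small heat shock proteins stood at a median of 6.90.

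In total 10579 probe sets passed at 30% inhibition against baseline, 5170 higher and 5409 lower, of which 1933 and 2022 changed at least 2-fold, and groups did not overlap for 10619, against 2.86% by chance. List calls that ended under other settings with the preset correlation, with the range of adjusted p over all alternatives with that correlation, were those of nitrogen assimilation (0.00159 to 0.0574) and flavonoid synthesis (9.15e-05 to 0.126) only above the upper quartile of signal, and of dehydration (0.000492 to 0.145) and NAC factors (0.00639 to 0.0878) with 1 probe set per gene. That of the clock (9.46e-06 to 0.0844) ended in both, and that of bZIP factors (0.0236 to 0.0866) with 1 probe set per gene or no filter. The GlutTrans and actin r2 control differences given above also separated the 4 arrays of this state from the 4 of baseline.

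From the optimum to 20% inhibition all 8 small heat shock protein probe sets rose. HSP22.5, below background on all 4 arrays of the optimum, was at least 53.7-fold higher (adjusted p = 4.64e-10), HSP17.5-E rose by 5.42 ± 0.18 and BAG6A by 5.41 ± 0.64, the latter with 1 of 4 arrays of the optimum below background. The list had 8 of 8 higher, also adjusted over the list alone (adjusted p = 1.49e-17; adjusted p = 0.0678 with an estimated correlation). MYB114 was at least 4.14-fold lower, PIP2-1 fell by 3.01 ± 0.89 and USP1 fell by 2.92 ± 0.59, each of the last 2 below background on 3 of 4 arrays at 20% inhibition. With signals below background set at that level, PIP2-1 changed by only -0.80 and USP1 by -1.46. HSF-26 and HSF-03 differed by -0.06 ± 0.28 and -0.19 ± 0.25 in this step and did not pass. The heat shock factor list rose at 2 of 14 (2 adjusted over the list alone; adjusted p = 0.0427; adjusted p = 0.583 with an estimated correlation). The HSP90 list had 3 of 10 higher (3 higher and 5 lower adjusted over the list alone), with a median of -0.23 and a mean of 0.37. Dehydration and abscisic acid genes rose at 2 of 8 (2 adjusted over the list alone; adjusted p = 0.0256; adjusted p = 0.357 with an estimated correlation). Nitrogen assimilation fell at 7 of 18 (7 adjusted over the list alone; adjusted p = 0.000991; adjusted p = 0.161 with an estimated correlation). Ribosomal proteins fell at 5 of 10 (5 adjusted over the list alone; adjusted p = 0.00857; adjusted p = 0.583 with an estimated correlation), and ubiquitin and proteasome genes fell at 6 of 16 (7 adjusted over the list alone; adjusted p = 0.00436; adjusted p = 0.272 with an estimated correlation). The clock and photoperiod list fell at 4 of 10 and rose at 1 (6 and 1 adjusted over the list alone; adjusted p = 0.00663; adjusted p = 0.266 with an estimated correlation). Flavonoid and phenylpropanoid synthesis fell at 10 of 57 and rose at 2 (13 and 2 adjusted over the list alone; adjusted p = 0.0105; adjusted p = 0.634 with an estimated correlation). Calcium signalling fell at 5 of 16 (5 adjusted over the list alone; adjusted p = 0.0373; adjusted p = 0.656 with an estimated correlation).

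The step from the optimum to 20% inhibition held 5059 probe sets past the threshold, 2403 higher and 2656 lower, with 602 and 621 changed at least 2-fold (994 lower without 20% inhibition replicate 4), and groups did not overlap for 6283 of 30517, against 2.86% by chance. Without the 3 arrays of highest background, all at the inhibited states, 2865 passed, and 2223 passed with background as a covariate, 477 higher and 376 lower by at least 2-fold. Without 20% inhibition replicate 3 alone, the array that stood apart above, 4065 passed. The call of PIP2-1 ended without optimum replicate 3 (-3.08) or 4 (-2.71), in the fit of only the 8 arrays compared (adjusted p = 0.0866) and without the 3 arrays of highest background (-1.63). Its change was -1.85 without 20% inhibition replicate 2 and -3.68 without 20% inhibition replicate 4, against -0.80 over all arrays with signals below background set at that level. USP1 changed by -2.15 without 20% inhibition replicate 3. Both calls ended with background as a covariate (PIP2-1 -2.59, USP1 -2.35). List calls also ended on leaving out an array. That of dehydration ended without optimum replicate 1 (adjusted p = 0.0784) and that of flavonoid synthesis without 20% inhibition replicate 4 (0.0704). That of heat shock factors ended without optimum replicate 3 (0.0563) or 4 (0.063) or 20% inhibition replicate 2 (0.0632) or 3 (0.0819), and that of calcium signalling without optimum replicate 1 (0.119) or 2 (0.0582) or 20% inhibition replicate 1 (0.0573), 2 (0.0527) or 4 (0.0814). With 1 probe set per gene the calls of ubiquitin and proteasome genes (2.68e-05 to 0.0628 over all alternatives with the preset correlation), dehydration (0.00845 to 0.163), the clock (6.58e-05 to 0.118), flavonoid synthesis (1.91e-05 to 0.169), calcium signalling (0.00297 to 0.704) and heat shock factors (0.0189 to 0.178) ended, and all of these but ubiquitin also ended only above the upper quartile of signal. With background as a covariate those of dehydration, calcium signalling and heat shock factors ended, and the last also with array weights or without the 3 arrays of highest background. Background and the actin r2 control difference, given above, were also higher at 20% inhibition than at the optimum in their means.

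Between 20% and 30% inhibition, limma called 0 of 30517 probe sets, with 1193 at an unadjusted p under 0.05. Those 1193 are a smaller share than the 0.05 that chance alone gives. HSP17.5-E, HSP90A1 and HSF-08 differed by -0.10 ± 0.18, -0.10 ± 0.27 and 0.29 ± 0.33, and LHY by -0.28 ± 0.16. HSP17.5-E and HSP90A1 were among the brightest signals of the arrays at both states, where a further rise may not show. The 95% interval of the difference lay within 1 log2 unit of 0 for 77.3% of probe sets tested, and for 95.5% of those above the upper quartile of signal. Groups did not overlap for 628 of 30517 probe sets, against 2.86% by chance. As lists, nitrogen assimilation was shifted up with a median of 0.24 (adjusted p = 0.0427; adjusted p = 0.327 with an estimated correlation). Jasmonate and wounding was shifted down with a median of -0.09 (adjusted p = 0.0395; adjusted p = 0.678 with an estimated correlation). Limma called 0 members of either, also adjusted over the list alone. The nitrogen call ended without 20% inhibition replicate 1, 2 or 4 or 30% inhibition replicate 2, 3 or 4 (adjusted p = 0.0598 to 0.219). The jasmonate call ended without 20% inhibition replicate 1, 2 or 4 or 30% inhibition replicate 2 or 3 (0.0527 to 0.477). Both ended with 1 probe set per gene, nitrogen also without the 3 arrays of highest background (0.00466 to 0.27 over all alternatives with the preset correlation), and jasmonate with quantile normalization, no filter or no trend of the prior variance (0.00125 to 0.477). Over all 5 contrasts camera called 38 of 170 pairs of list and contrast, and 0 with an estimated correlation.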

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

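The tests on the upper quartile of signal, on the median change of all probe sets, on the 3 arrays of highest background, on the control probe sets and on the LHY-type genes between 20% and 30% inhibition were chosen only after the result was seen.

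Single arrays stood apart from the other 3 of their state by Dixon's test in 18 of 420 groups of 4 values, where chance gives about 1 in 20, and optimum replicate 1 held 3 of them. The values below are log2 signals, with the range of the other 3 arrays in brackets. At baseline, MYB114 stood at 12 on replicate 3 (11.52 to 11.59), SODB2 at 15.45 on replicate 3 (15.18 to 15.21), IFS1 at 10.63 on replicate 4 (10.8 to 10.83) and CYP11 at 11.78 on replicate 4 (11.44 to 11.46). At the optimum, HSP22.3 stood at 10.1 on replicate 1 (9.86 to 9.89), CCT-D at 10.93 on replicate 1 (10.73 to 10.76) and WRKY8 at 6.28 on replicate 2 (6.82 to 6.9). On optimum replicate 3, MYB177 stood at 3.63 (6.39 to 6.74) and SB100 at 8.87 (9.62 to 9.76), and on optimum replicate 4, PIP2-1 stood at 8.67 (7.39 to 7.55) and APX1 at 14.13 (14.59 to 14.67). At 20% inhibition, ERD15 stood at 12.75 on replicate 1 (12.43 to 12.47), GSTU3 at 11.78 on replicate 3 (12.65 to 12.74), BMY2 at 12.23 on replicate 3 (11.82 to 11.85) and CYP17 at 11.07 on replicate 4 (11.25 to 11.28). At 30% inhibition, WRKY8 stood at 6.96 on replicate 1 (6.26 to 6.35) and GSTU28 at 10.77 on replicate 4 (12.54 to 12.81). The actin r2 difference between 3′ and 5′ probe sets was 0.95 on optimum replicate 1 (1.24 to 1.26).

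Some control probe sets, which no comparison of genes uses, also moved with the state. The 3′ minus 5′ log2 signal of actin r2 was higher than at baseline by 0.313 at 20% inhibition and by 0.282 at 30% inhibition. That of GlutTrans was higher by 0.736 at the optimum, 0.827 at 20% inhibition and 0.763 at 30% inhibition. For each of these the exact permutation p was 0.0286, the smallest that 4 against 4 arrays can give, and 0.129 after adjustment over 27 tests. The difference of the other actin set was lower at 20% inhibition than at baseline (-0.847, exact permutation p = 0.0571). Those of GAPDH (3′ minus M), ubiquitin and SucBP had exact permutation p of at least 0.343, with a wide spread for ubiquitin and SucBP.

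The first pattern is the extent of the response, with 10579 probe sets, 34.67% of those tested, past the threshold at 30% inhibition against baseline. Chance is argued against for each comparison with calls, since 1 of 35 splits of the 8 arrays, the real one, gave as many in each: 3932 at the optimum (highest other 24), 10863 at 20% inhibition (86), 10579 at 30% inhibition (1) and 5059 between 20% inhibition and the optimum (5), and for the F-test 1 of 100 splits (10829, highest other 2). A share of 1 in 35 is the smallest these splits allow, and it was not adjusted over the comparisons. The other splits mix arrays of differing states, which widens the spread, so their counts are no level for arrays without a difference. Array background that is higher in the inhibited states stays open as a cause. It moves dim probe sets most, and 48.87% of those above the upper quartile of signal passed. The share was also higher there at the optimum against baseline (21.38%, against 12.88% of all tested), where background differed little. Bright probe sets thus passed more often in either case, so this test cannot decide. Scaling to a common mean while heat shock transcripts take a growing share of the signal would lower the other probe sets by a common factor. The median change of all probe sets was -0.008 (middle 50% of values from -0.424 to 0.395), against a median of -0.835 for those called lower. No common fall of that size was thus seen in the scaled values. Scaling to a common mean can itself bring the middle of the changes near 0, however. A factor offset by a general rise would not show, so this explanation stays open. Part of the difference may come with background, since with background as a covariate 8262 probe sets passed, and 7070 at 20% inhibition against 10863 without, and what caused these lower counts stays open.

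The second pattern is that limma called 0 probe sets between 30% and 20% inhibition, with 1193 at an unadjusted p under 0.05, a smaller share than chance alone gives. All 35 splits of the 8 arrays gave at least 0, which any split does, so they exclude nothing. The highest other, 132, put 30% inhibition replicates 1 and 3 with 20% inhibition replicates 1 and 4, which points to a structure of the samples that was not tested. The second component of variation, 12.3% of the variance, put these same arrays above 0 and the others of the 2 inhibited states below. It comes from the same values and is no separate evidence. Noise of the 3 arrays with the highest background stays open: without them 2 probe sets passed and 2433 had an unadjusted p under 0.05, with 2 arrays left at 20% and 3 at 30% inhibition. Too wide a spread to see a change of 2-fold stays open: the 95% interval lay within 1 log2 unit of 0 for 77.3% of probe sets, between the bounds set for either answer, though for 95.5% of those above the upper quartile of signal. A similar response at the 2 inhibited states is the biological explanation that the design offers, and it stays open.

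The third pattern is the fall of the LHY-type clock genes, whose 4 probe sets had a median log2 change of -4.01 at 30% inhibition against baseline. A loss of signal of bright probe sets in general is argued against by 12014 other probe sets as bright at baseline, whose median change was -0.119 (middle 50% of values from -0.511 to 0.255). The temperature curve lasted 3 to 4 h, so time of day moving on along it may account for the fall, as LHY is a morning gene. From 20% to 30% inhibition the median change of these probe sets was -0.154, which decides neither way. Heat and time of day cannot be told apart here, because no arrays without warming were taken at the later times.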

How the results depend on the processing

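Alternatives chosen only after the data were seen were background as a covariate, leaving out the 3 arrays of highest background, testing only IDs that begin with Gma, GmaAffx or soybean, and quantile normalization with the upper quartile. For the contrasts other than 30% against 20% inhibition, counts of probe sets past the threshold stayed within 1.5 times of those reported, with these exceptions: with background as a covariate 7070 at 20% inhibition against baseline (10863 without), 2223 between 20% inhibition and the optimum (5059 without) and 6960 by the F-test (10829 without), and without the 3 arrays of highest background 2865 between 20% inhibition and the optimum. That last fit left 2 arrays at 20% inhibition, and the cause of the lower counts was not tested. Without the same arrays 2 probe sets passed between 30% and 20% inhibition, where limma called 0 under each other alternative run. In the reported fit 1193 had an unadjusted p under 0.05, a smaller share than chance alone gives. Of 170 pairs of list and contrast 38 passed, but 9 with a single probe set per gene, where fewer members are tested and the 8 calls of small heat shock proteins, HSP90 and ribosomal proteins, with under 5 genes, could not be tested, and 0 with an estimated correlation. The 9 were ER protein folding (optimum and 30% inhibition against baseline), heat shock factors and flavonoid synthesis (20% and 30% inhibition against baseline) and nitrogen assimilation (20% and 30% inhibition against baseline, and 20% inhibition against the optimum).

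With each array of the states compared left out in turn the counts ran from 2735 to 3637 at the optimum, 9479 to 10978 at 20% inhibition, 9102 to 9839 at 30% inhibition, 3731 to 5494 between 20% inhibition and the optimum, 0 to 0 between 30% and 20% inhibition, 9198 to 11302 by the F-test, and 34 to 47 for pairs of list and contrast. Leaving out arrays of the other states, which share the estimate of the spread, gave up to 4329 at the optimum and 11149 at 30% inhibition, both without 20% inhibition replicate 3. Of 125 results for named genes, 104 kept their side of the threshold in every alternative run on them. Of the 38 pairs of list and contrast, 14 kept it in every alternative with the preset correlation, and 0 with the estimated one. The named genes missed the threshold in 63 fits that left out 1 array and in 48 others, 19 of these with background as a covariate, and H4 passed in the fit of only the 8 arrays compared. The pairs missed it in 30 and 58 with the preset correlation. Direction reversed in 0 of the called results, while LOXB1 and VSPA, which were not called, changed sign, LOXB1 to -0.04 with quantile normalization and VSPA to 0.01 with background as a covariate.

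The replicate number as a block gave 3558, 10473, 10162, 4578 and 0 probe sets in the order of the contrasts, 10134 by the F-test and 38 pairs of list and contrast. It ended the calls of ADR12, AOX2, NAC018 and SCAM-2 and changed no other call of a named gene or list. Arrays with the same number had a median residual correlation of 0.053 (-0.278 to 0.217), 7 of 24 above 0.1, and 8 of 16 arrays matched best with their own number. Signal over background limits what can be seen: on the single arrays 68.4% to 78.8% of probe sets with soybean IDs lay above the background level, which ran from 74.5 to 163, while the filter stood at a signal of 67.6.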

Other observations

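The gene families below lie outside the lists fixed before the data were examined. They were chosen after seeing the data, by shared symbols with at least 5 genes tested, and no test of the families as groups was made. Of all probe sets tested, 34.67% passed at 30% inhibition against baseline, so a count near that share is no response particular to a family. At 30% inhibition against baseline, 3 of 9 aldehyde dehydrogenase genes rose and 1 fell, with ALDH3H1 up by 1.52 ± 0.42, ALDH10A2 by 1.04 ± 0.15 and ALDH7B1 by 0.76 ± 0.13, while ALDH2C8 fell by 0.99 ± 0.31 (log2 change ± standard error, n = 4 arrays per state). Of 21 cytochrome P450 genes with CYP symbols 6 rose and 6 fell. CYP82A2 and CYP82A3 rose by 2.29 ± 0.55 and 1.56 ± 0.33, while CYP76O2 fell by 1.94 ± 0.58 and CYP72A67 fell by 1.53 ± 0.17. CYP97C10, of a family that hydroxylates carotenoids, changed by -1.28 ± 0.23.

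Of 5 SWEET sugar transporter genes 2 fell and 0 rose, SWEET28 by 2.06 ± 0.24 and SWEET34 by 1.51 ± 0.16. Of 5 WNK kinase genes 3 fell and 0 rose, WNK13 by 1.62 ± 0.26, WNK8 by 0.82 ± 0.19 and WNK1 by 0.58 ± 0.13. Gene entries named OAS-TL, for enzymes of cysteine synthesis, had 3 of 7 higher and 3 lower, 2 of the higher ones sharing the symbol OAS-TL1, with 1 of these up by 0.68 ± 0.13 and OAS-TL6 down by 1.53 ± 0.21. Genes named PHR had 2 of 9 higher and 3 lower, with PHR13 up by 0.77 ± 0.13 and PHR at -2.32 ± 0.36. Of 6 genes named PAP 1 rose and 1 fell, PAP02 by 0.49 ± 0.16 and PAP by 1.15 ± 0.25.

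Probe sets whose IDs begin with PsAffx or HgAffx are paired with no gene in the annotation, and 529 and 306 of them were tested. At 30% inhibition against baseline 26 and 5 of them were higher and 5 and 0 lower, and at 20% inhibition 34 and 13 were higher and 2 and 0 lower. Without the 3 arrays of highest background, an alternative chosen after seeing the data, the probe sets past the threshold between 30% and 20% inhibition were 2, at 3.10 ± 0.40 and 6.36 ± 0.68, both without a gene in the annotation.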
